A study of Homo sapiens and Mus musculus with 24 samples.

How the data were processed

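Chromatin immunoprecipitation followed by sequencing was measured in fetal liver of WT and hemogen KO mouse embryos at day 14.5. The protocols in the labels describe formaldehyde fixation, sonication and precipitation, with libraries made either by tagmentation on beads or with a ligation kit; which of these served each library is not stated there. Bowtie2 2.3.5, SAMtools 1.9, Picard 2.21.4 and MACS2 2.2.7.1 are named in the submitters' processing notes, with no role or order. The genome build, the read filters and the control of each call are not given in the sources used here. Contig names such as chr4_GL456216_random and peaks on chromosome 1 up to position 195241899 fit the mouse build mm10 (GRCm38). The build is inferred from the files, and no position was converted to another build.

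The authors deposited 1 peak list for each of 8 libraries and 1 for each of 4 groups, with no header. Each peak in the authors' lists carries a fold enrichment (a ratio to local background), a −log10 p-value and a −log10 q-value. The smallest −log10 q in any list lay between 1.30 and 1.37. Fold and p-values are the authors' own, and served to describe, rank and filter peaks within a list. Groups and replicate numbers came from the sample titles. Peaks on the 19 autosomes and chromosome X were kept, and between 0 and 10 peaks per list on other sequences were left out of the comparisons.

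Peaks overlapping by 1 bp were counted as shared. Regions of a group are merged peaks of its 2 libraries with at least 1 peak of each. Strength is the mean percentile of −log10 p within the 2 library lists. A WT BRG1 region counted as called in the KO when it overlapped a peak of either KO library or of the KO group list; a region not called is not thereby unbound. Odds ratios are Mantel-Haenszel values over 10 strata of WT strength, or over 5 strata of H3K27ac region width for co-occupancy, with 95% intervals from 1000 bootstrap draws of 1 Mb genome bins. These intervals describe regions, not animals. Circular shifts moved 1 list along each chromosome, 100 times for replicates and 1000 times for co-occupancy. Peak numbers of 2 against 2 libraries were compared by an exact permutation test.

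Depth was recovered from the authors' values by taking the p-value as an upper Poisson tail and the fold as height plus 1 over background plus 1. Up to 6000 peaks per list were used. Summit heights then came out as whole multiples of 1 scaling factor, within 0.01, for 100% of peaks in 11 of the 12 lists and for 84.8% in the hemogen group list. The lowest background shared by at least 5 peaks, divided by the shortest peak width as the fragment length, gave the depth of calling. Dividing this by the scaling factor as well gave the depth of the immunoprecipitate. Both were set relative to WT BRG1 library 1. This reading of the formula is an assumption about the caller. The depth of the immunoprecipitate came to 2.02 for the WT BRG1 group list and 0.738 for the KO group list. Single libraries came to 1.00 and 1.04 in WT, and to 0.406 and 0.342 in the KO. The depth of calling was 0.861 for library 2 of WT BRG1 and of hemogen and 0.860 for library 2 of H3K27ac. For library 1 it was 1.00 for WT BRG1, 0.817 for hemogen and 0.898 for H3K27ac. Which lists share an input is not given in the sources used here.

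On simulated data with odds ratios of 0.5, 1 and 4 over 13000 regions, the mean estimate was 0.502, 0.988 and 4.04. The true value lay in 36, 33 and 38 of 40 intervals, so the intervals may be somewhat too narrow. The simulation used fewer bootstrap draws than the data and an assumed spread between bins, so the coverage of the reported intervals was not measured. Overlaps of 12000 simulated peaks matched a direct comparison with 0 differences, and the simulated depth scale was recovered in 4 settings. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.

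The tests, the overlap rule and most alternatives were set before the data were examined. The alternatives were group lists, an overlap of 50% of the shorter interval, a minimum −log10 q of 5, each library left out, a call in both KO libraries, BRG1 lists trimmed to 3205 peaks, 20 strata, no strata, and replicate number as a stratum. A mouse annotation and genome were not used here. For that reason the promoter strata, the promoter comparison, the genomic distribution, the tests of 14 gene lists, the motif search and the part of the naming rule that needs genes were left out, and regions are named by position. The rule named the 5 strongest WT BRG1 regions in no KO list with hemogen, the 5 strongest without, and the 5 strongest KO regions in no WT list. The H3K27ac and strong-hemogen odds ratios, the trimmed WT comparison, the depth recovery and the stitched domains were added after the data were seen.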

Results

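The series asks where hemogen, the chromatin remodeller subunit BRG1 and acetylated histone H3 lysine 27 (H3K27ac) lie in erythroid chromatin, and what becomes of BRG1 without hemogen. Hemogen is a nuclear protein of blood-forming cells, BRG1 is the ATPase of BAF (SWI/SNF) remodelling complexes, and H3K27ac marks active promoters and enhancers. The 12 mouse samples came from livers of embryos at day 14.5, when the fetal liver is a main site of red cell formation. They comprised 2 libraries each of wild-type (WT) hemogen, H3K27ac and BRG1 immunoprecipitates, of BRG1 immunoprecipitates from hemogen knockout (KO) embryos, and of input from both genotypes. Hemogen was precipitated with an antibody against the HA tag from livers labelled WT. The labels do not say how the tag was introduced, and every hemogen peak rests on it; an HA precipitate from untagged liver was not analysed here. Each of the 8 immunoprecipitates had a list of peaks, and each of the 4 groups a group list. The 12 libraries of human K562 cells, an erythroleukaemia line, were not analysed here. The labels do not say whether libraries came from separate animals, so all spreads below are between libraries and may be technical.

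The WT BRG1 lists held 26330 and 21167 peaks in libraries 1 and 2, the hemogen lists 53063 and 42871, and the H3K27ac lists 69883 and 45548. The KO BRG1 lists held 3209 and 5602 peaks. The authors' median fold enrichment per list lay between 3.83 and 4.55 in the library lists. Depth behind the lists was unequal. Recovered from the authors' fold and p-values and set relative to WT BRG1 library 1, the depth of the immunoprecipitate was 1.04 in WT BRG1 library 2 but 0.406 and 0.342 in the KO BRG1 libraries. The scaled depth at which peaks were called was 0.861 in WT BRG1 library 2 and 0.259 and 0.262 in the KO libraries.

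**Figure D1:**
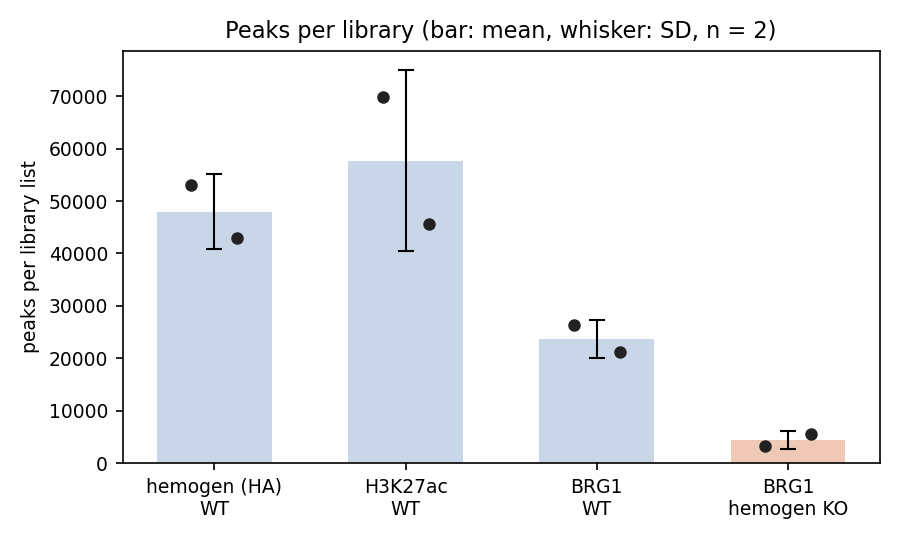
Number of peaks in each library list (vertical axis) for the 4 immunoprecipitated groups; points are libraries, bars the mean and whiskers the SD of 2 libraries. The KO BRG1 libraries, with 3209 and 5602 peaks, lie below both WT BRG1 libraries, with 26330 and 21167.

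Peaks of the 2 libraries of a group overlapped far more often than shifted lists. Of the peaks in WT BRG1 library 2, 81.0% overlapped a peak of library 1 by at least 1 bp, and 58.4% of those in library 1 overlapped library 2. The corresponding shares were 78.0% and 58.1% for hemogen and 63.5% and 40.2% for H3K27ac. In the KO, 52.3% of the peaks of BRG1 library 1 lay in library 2 and 28.9% of those of library 2 in library 1. At a minimum −log10 q of 5 these KO shares were 30.1% and 11.5%. Shifting the other list along each chromosome gave at most 2.83% in any of 100 shifts of any group. Merged peaks found in both libraries, called regions below, numbered 25631 for hemogen, 25305 for H3K27ac, 13213 for WT BRG1 and 1543 for KO BRG1.

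Most BRG1 regions in WT liver overlapped hemogen. Of the 13213 WT BRG1 regions, 12763 (96.6%) overlapped a hemogen region and 8442 (63.9%) an H3K27ac region. Circular shifts gave at most 3.16% and 2.60% in 1000 draws. Shifts move peaks to any part of a chromosome, so they do not test overlap beyond that of any lists from active chromatin. Of the 25631 hemogen regions, 10675 (41.6%) overlapped a BRG1 region. Among the 25305 H3K27ac regions, 9182 held both factors, 3212 hemogen alone, 227 BRG1 alone and 12684 neither. BRG1 was present at 74.1% of the H3K27ac regions with hemogen and at 1.76% of those without. The Mantel-Haenszel odds ratio of co-occupancy over quintiles of region width was 142 (95% interval 125 to 166, 1000 bootstrap draws of 1 Mb bins). The strength of H3K27ac was not held. An input shared by hemogen and BRG1 lists, which no source states, was not tested for this value. The hemogen lists were longer than the BRG1 lists. With every WT library list trimmed to its strongest 21165 peaks, an alternative chosen after the data were seen, 83.2% of BRG1 regions overlapped hemogen, 62.5% of hemogen regions overlapped BRG1 and 39.5% of BRG1 regions overlapped H3K27ac. The odds ratio was then 40.05 (35.0 to 45.8). Against the longer group lists, 99.7% of BRG1 regions overlapped hemogen, 71.9% of hemogen regions overlapped BRG1 and 89.9% of BRG1 regions overlapped H3K27ac, so these shares depend on list length. Without WT BRG1 library 2 the odds ratio was 71.2, without library 1 it was 90.9, and at a minimum −log10 q of 5 it was 33.9.

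Hemogen regions shared with BRG1 were stronger and far more often acetylated. H3K27ac covered 7795 of the 10675 hemogen regions with BRG1 (73.0%) and 2413 of the 14956 without (16.1%), a difference of 56.9 percentage points (95% interval 55.7 to 58.0; Fisher's exact test, two-sided, over regions, odds ratio 14.1, −log10 p = 1912). Strength was defined as the mean percentile of the authors' −log10 p within the 2 library lists. It had a median of 83.6 in hemogen regions with BRG1 and 51.0 in those without. At like hemogen strength the odds ratio of acetylation with BRG1 remained 9.88 (9.14 to 10.7). The share of hemogen regions holding BRG1 was 8.58% in the weakest decile of hemogen strength and 94.7% in the strongest, and the share with H3K27ac was 15.9% and 74.8%. In library 1, the summits of overlapping hemogen and BRG1 regions lay a median of 288 bp apart, and 26.8% lay within 100 bp.

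The KO libraries held fewer BRG1 peaks than the WT libraries. The number per library was 23747 ± 3652 in WT and 4399 ± 1688 in the KO (SD, n = 2 libraries each), a ratio of 5.40. Both KO libraries lay below both WT libraries, which gave p = 0.33 in an exact two-sided permutation test; this is the smallest p that 2 against 2 libraries allow. Depth differed in the same direction, as given above. At a minimum −log10 q of 5 the ratio was 10.6. Most KO peaks lay at WT positions: 98.0% and 95.9% of the peaks of KO libraries 1 and 2 and 89.1% of the 13938 peaks of the KO group list overlapped a WT BRG1 peak of any list.

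Of the 13213 WT BRG1 regions, 7306 (55.3%, 95% interval 54.2 to 56.3 over genome bins) were called in at least 1 of the 3 KO lists, and 5907 were in none. KO library 1 held 18.4% of the 13213, KO library 2 28.9%, both libraries 12.1% and the group list 53.6%. A region can count in more than 1 of these shares. The call depended on strength. It was made at 25.9% of the regions in the weakest decile of WT strength and at 91.6% of those in the strongest. On the authors' group lists, 24.6% of WT peaks were called in the KO. Without WT BRG1 library 2 the share was 35.0%, and without KO library 1 or 2, with the group list also left out, it was 28.9% or 18.4%.

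**Figure D2:**
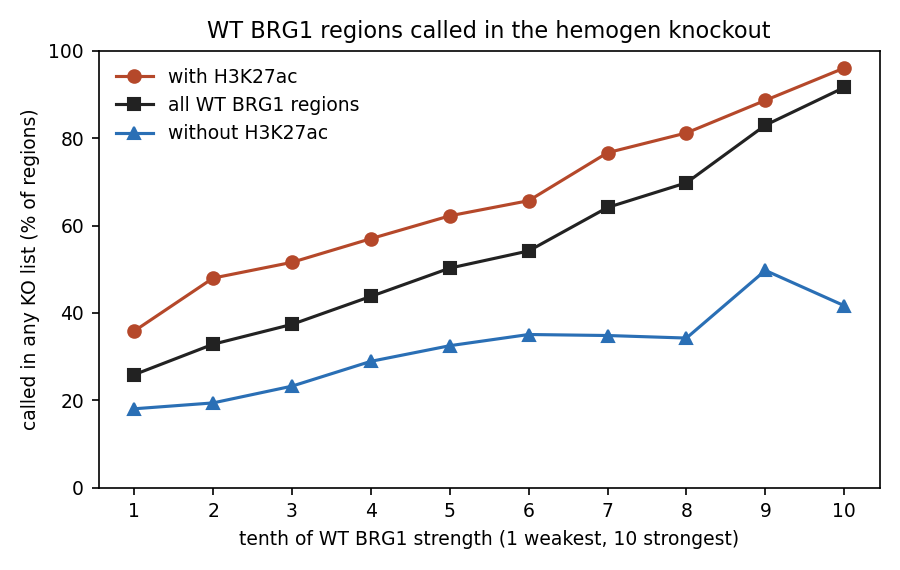
Percent of WT BRG1 regions called in any KO BRG1 list (vertical axis) by decile of WT BRG1 strength (horizontal axis, 10 strongest) for all regions and for those with and without H3K27ac. In the strongest decile 96.0% of the 1214 regions with H3K27ac and 41.7% of the 108 without were called. With H3K27ac means overlap with an H3K27ac region found in both libraries.

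The planned comparison by hemogen occupancy rested on few regions, since only 450 WT BRG1 regions lacked a hemogen region found in both libraries. Of all WT BRG1 regions, 99.7% overlapped the longer hemogen group list, so most of the 450 overlapped a peak of that list. Among the 450, 147 (32.7%) were called in the KO, against 7159 of the 12763 with hemogen (56.1%). Regions without hemogen were weaker, with a median strength of 34.9 against 64.0. Over deciles of WT strength the odds ratio of being called with hemogen was 1.20 (0.961 to 1.49), an interval that includes 1. It was 2.87, 2.24, 2.47 and 2.17, each with an interval above 1, in the 4 pairs of a single WT and a single KO library (1 with 1, 1 with 2, 2 with 1, 2 with 2). It was 2.63 with no strata, 2.09 on group lists and 0.931 (0.758 to 1.16) at a minimum −log10 q of 5. Leaving out WT BRG1 library 1 gave 1.97 (1.72 to 2.27) and leaving out library 2 gave 2.09 (1.87 to 2.33), both past the threshold; so was the 1.38 (1.06 to 1.81) without hemogen library 2.

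Acetylated BRG1 regions kept their BRG1 call far more often. This comparison and the next were chosen after the data were seen. Of the 8442 WT BRG1 regions with H3K27ac in WT, 70.7% were called in the KO, against 28.1% of the 4771 without. Without means no overlap with an H3K27ac region found in both libraries. The longer H3K27ac group list overlapped 89.9% of WT BRG1 regions, so most of the 4771 overlapped a peak of that list. At like WT BRG1 strength the odds ratio was 4.19 (3.85 to 4.57). It was 2.83 (2.58 to 3.11) with strata of hemogen strength and region width added, 7.96 on group lists, 8.61 with BRG1 lists trimmed to equal length and 2.42 at a minimum −log10 q of 5. Of the 1543 KO BRG1 regions, 92.4% overlapped WT H3K27ac and 98.5% WT hemogen. These shares were not matched for strength. In the strongest decile of WT BRG1 regions 1214 of 1322 overlapped H3K27ac, and 96.6% of all WT BRG1 regions overlapped hemogen. H3K27ac in the KO liver was not analysed here.

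BRG1 regions with the strongest hemogen were called least often in the KO. Within each decile of WT BRG1 strength, regions with hemogen were split into quintiles of hemogen strength. The called share, averaged over deciles, was 62.9%, 64.8%, 59.2%, 51.5% and 38.8% from the weakest to the strongest quintile. The odds ratio above against below the median was 0.457 (0.419 to 0.496), and 0.481 (0.439 to 0.526) with strata of H3K27ac and width added. Both strengths here averaged libraries 1 and 2. With BRG1 strength from 1 WT library and hemogen strength from the library of the other number, the odds ratio in each KO library lay between 0.935 and 1.01, and all 4 intervals included 1. With hemogen strength from the library of the same number it was 0.965 and 0.939 for number 1, with intervals including 1, and 0.778 and 0.743 for number 2, with intervals below 1. Over regions or peaks scored with both hemogen libraries it was 0.801 with replicate number as a stratum and 0.888 with no strata. Scored so, WT library 1 gave 0.869 and 0.816 against KO libraries 1 and 2, and WT library 2 gave 0.808 and 0.759. Each of these 4 pairs had an interval below 1.

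The peaks of 1 WT BRG1 library were also scored against the other WT library trimmed to the length of each KO list. Trimming matches the length of the lists but not their depth. For strong hemogen the odds ratio was then 1.71 to 3.35, against 0.743 to 1.01 for the KO lists. For H3K27ac it was 1.47 to 2.75, against 4.59 to 6.52 for the KO lists. The 95% intervals of the KO and WT outcomes were apart in 8 of 8 combinations for both marks.

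**Figure D3:**
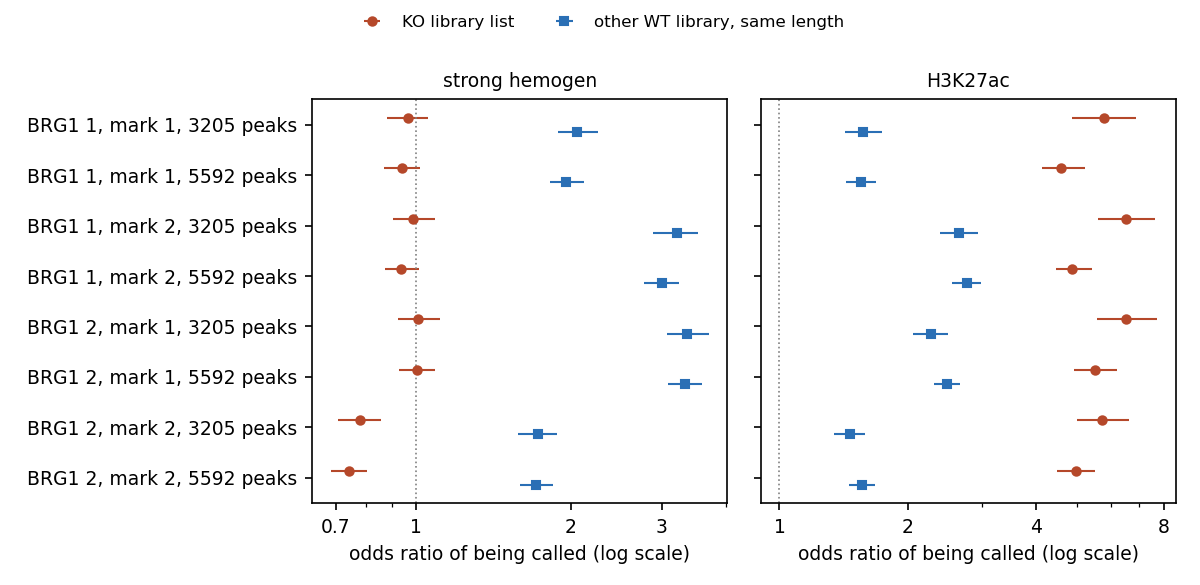
Odds ratio of a WT BRG1 peak being called (horizontal axis, log scale, with 95% intervals) for strong against weak hemogen (left) and for H3K27ac against none (right), at like BRG1 strength. Each row names the WT BRG1 library, the library of the mark and the list length of 3205 or 5592 peaks; circles are KO lists and squares the other WT library trimmed to that length.

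Coordinates below are 1-based, with no gene assigned. No source names the build; the contig names and positions fit mm10. The 5 strongest WT BRG1 regions with hemogen and in no KO list lay at chromosome 3 from 35923133 to 35924373, chromosome 3 from 95216700 to 95218236, chromosome 4 from 87805997 to 87806916, chromosome 11 from 95800067 to 95801181 and chromosome 11 from 86742580 to 86743005. Their WT strength percentiles ran from 99.6 to 98.3. The first had authors' folds of 7.44 and 11.4 in WT libraries 1 and 2. The second and the fourth overlapped H3K27ac. The 5 strongest without hemogen in no KO list were weaker, with percentiles from 77.1 to 69.4; the strongest lay at chromosome 2 from 127269569 to 127270086, and the next at chromosome 7 from 19458275 to 19458799. The others lay at chromosome 1 from 134075935 to 134076450, chromosome 10 from 58255315 to 58255827 and chromosome 3 from 95520232 to 95520716.

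Only 4 of the 1543 KO BRG1 regions overlapped no WT BRG1 peak of any list. Those at chromosome 10 from 20149341 to 20149641 and chromosome 16 from 30550493 to 30550703 had authors' folds of 5.91 and 3.99, and of 4.71 and 4.67, in KO libraries 1 and 2, and overlapped a hemogen peak of some WT list. Those at chromosome 17 from 39847612 to 39847947 and chromosome 11 from 3193078 to 3193704 had folds of 1.77 and 1.86, and of 2.26 and 1.98, against a median of 4.32 and 4.41 over all KO regions.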

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

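BRG1 peaks of the KO libraries also lay on the unplaced sequence chrUn_JH584304, which the comparisons left out: 4 peaks in KO library 1 and 10 in KO library 2, against 0 in both WT BRG1 libraries. The largest authors' fold there was 3.19 and 5.17 in KO libraries 1 and 2. No explanation of this was tested.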

How the results depend on the processing

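The co-occupancy odds ratio kept its direction and its side of the threshold in 11 of 11 alternatives (33.9 to 162), the acetylation difference in 9 of 9 (42.7 to 57.9 points), and the added odds ratios for H3K27ac (2.42 to 8.61) and strong hemogen (0.439 to 0.888) in 15 of 15 each. Single WT libraries scored against single KO lists, which are not among these 15, gave strong-hemogen values nearer to 1. With hemogen strength from both libraries these were 0.759 to 0.869, with intervals below 1. With crossed libraries they were 0.935 to 1.01, with intervals including 1. Uncrossed they were 0.965 and 0.939 for library 1, also with intervals including 1, and 0.778 and 0.743 for library 2. The share of WT BRG1 regions called in the KO moved to 24.6% on group lists and 38.6% at a minimum −log10 q of 5. It was 12.1% for a call in both KO libraries, and 18.4% to 41.6% when 1 library was left out. With BRG1 lists trimmed to 3205 peaks, and the KO group list not used, it was 69.6% of 1700 regions. Those regions come from the strongest WT peaks, which were called more often, so this is not a like share. The odds ratio of hemogen-occupied regions passed the threshold on group lists (2.09) and with no strata (2.63), turned to 0.931 at a −log10 q of 5 with an interval including 1, and ran from 1.06 to 2.09 when 1 library was left out. Dropping the strength strata removes the match on strength by construction; the cause of the other moves was not tested. The ratio of WT to KO BRG1 peaks was 10.6 at a −log10 q of 5 and 4.25 to 7.41 with 1 library left out. Requiring 50% overlap lowered the replicate shares of the shorter list to 73.8% for WT BRG1, 44.1% for KO BRG1, 70.8% for hemogen and 56.9% for H3K27ac. At a −log10 q of 5 they were 79.6%, 30.1%, 80.1% and 56.9%.

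With the replicate block, pairing WT and KO libraries by number, the odds ratio was 2.40 for hemogen occupancy, past the threshold, 0.801 for strong hemogen and 5.13 for H3K27ac. The 2 libraries of each group share only a number, and this fit uses peaks of single WT libraries, not regions found in both. Promoter windows, gene assignment, gene backgrounds and motif windows were not run, since they need an annotation or genome not used here; replicate overlap has no value with 1 library left out. Relative to WT BRG1 library 1, the KO library lists were called at a depth of 0.259 and 0.262 and the KO group list at 0.517; no detection limit was measured.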

Other observations

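The number of BRG1 peaks per library was a planned comparison. All other patterns below, and the domains, were taken up after the data had been seen. The tests of depth, of H3K27ac with region width, and of domains with hemogen strength or single libraries were chosen only after the result was seen; the other tests were written down before their own results, but after the patterns they bear on.

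WT H3K27ac regions less than 12.5 kb apart were joined into 7887 domains. By covered length the largest lay at chromosome 2 from 27958534 to 28114005, with 96 H3K27ac, 8 hemogen and 6 BRG1 regions. The next lay at chromosome 8 from 120357723 to 120502412, with 76, 12 and 9, and at chromosome 10 from 80016766 to 80171028, with 66, 20 and 14. In the fourth, at chromosome 11 from 31709431 to 31873316, 6 of 14 BRG1 regions were called in the KO, against 3 of 6, 8 of 9 and 12 of 14 in those on chromosomes 2, 8 and 10. In the fifth, at chromosome 2 from 153474648 to 153613405, 10 of 13 were called. These domains were singled out after their values were seen.

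One hypothesis was that large acetylated domains lose BRG1 calls more often. Of 1882 acetylated BRG1 regions in the 394 largest domains, 64.9% were called in the KO, against 72.3% of 6560 others, and the odds ratio at like strength was 0.783 (0.669 to 0.90). Hemogen was stronger in these domains, with a median strength of 91.9 against 85.4, and with strata of hemogen strength added the odds ratio was 0.942 (0.812 to 1.09), an interval that includes 1. Single-library odds ratios were 0.838 to 0.931 for KO lists and 0.848 to 1.06 for the other WT library trimmed to the same length, with overlapping intervals in all 4 pairs. Domain size therefore cannot be told apart from hemogen strength, and a tie to the KO is not shown.

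BRG1 regions with stronger hemogen were called less often in the KO. The values argue against list length alone as the cause: a trimmed WT list gave an odds ratio of at least 1.71 (1.59 to 1.85). Trimming keeps the strongest peaks of a list called at greater depth, so it does not test lower depth. With strata of H3K27ac calls and region width, the KO odds ratio with averaged strengths was 0.481 (0.439 to 0.526), against 0.457 without them. This argues against these calls and width as the cause of the averaged value only. The strength of H3K27ac was not held, and these strata were not added to the crossed-library values. An input shared by same-numbered WT lists, which no source states, may account for the value lying below 1. With crossed libraries the odds ratio came to as much as 1.01 (0.922 to 1.12). This cannot be told apart from the looser match that strength from 1 library gives. Crossed values also rest on single WT and KO lists, which with hemogen strength from both libraries gave 0.759 to 0.869. Uncrossed values of library 1 also had intervals including 1, while those of library 2 were 0.778 and 0.743, with intervals below 1. What stays open is the contrast between KO and trimmed WT lists. Loss of hemogen, lower depth in the KO and a difference in immunoprecipitation are among the candidates that these lists cannot separate. Whether WT and KO libraries were made by the same library method is not stated either.

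A further hypothesis was that the called share falls at each step of hemogen strength in both KO libraries. It was not borne out: the share rose at 2 of 8 steps between quintiles, both from the weakest to the next.

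BRG1 regions with H3K27ac were called more often in the KO. Shorter lists reach an odds ratio of at most 2.75 (2.55 to 2.98) in WT, below the KO values of 4.59 to 6.52. The shared input leaves the lowest crossed value at 4.87 (4.46 to 5.42). The genotype, the lower depth of the KO libraries and a difference in immunoprecipitation between the KO and WT libraries all stay open, as untested. So does a difference in library method, which the labels do not assign, and this list may not be complete.

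Fewer BRG1 peaks in the KO cannot be told apart from lower depth. If enrichment were unchanged, the WT counts predict that KO libraries 1 and 2 call 70.9% and 82.4% of the strongest decile of WT library 1 peaks; 44.1% and 58.9% were called. The called share of the strongest decile fell below the predicted one in 4 of 4 pairs of libraries. Over all peaks of WT library 1 the prediction was 18.3% and 28.7% for KO libraries 1 and 2, and 9.90% and 16.7% were called. For WT library 2 it was 22.2% and 33.0%, against 12.4% and 20.4%. Over all peaks the prediction was too high between WT libraries as well, so a shortfall there is not particular to the KO. From WT library 1 to WT library 2 the prediction was 99.99% against 98.9% seen in the strongest decile, where nearly all peaks were called, and 86.6% against 58.4% over all peaks. From WT library 2 to WT library 1 it was 99.998% against 99.86% in the strongest decile and 96.6% against 81.0% over all peaks. The prediction is simulated from an assumed noise model, so depth stays open.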
